A study of Ptychodera flava with 31 samples.

How the data were processed

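RNA was measured in whole wild-type animals of Ptychodera flava at 16 stages in 31 libraries, 1 to 3 per stage. Per the labels, RNA was extracted with the RNeasy Micro kit and polyA-selected, strand-specific libraries were made with the TruSeq Stranded mRNA kit. The labels call the libraries of a stage biological replicates but give no parents or cultures, so that p-values measure the spread between these samples. Stage and replicate number were taken from the sample titles.

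The deposited files hold 1 table per library with estimated counts (expected counts, fractional where reads were shared between models). The deposited files also hold TPM, the share of transcripts after scaling by effective length. Per the file headers, 2 other columns hold the length and the effective length of each transcript model. kallisto and edgeR are named by the authors, and their versions, the genome build and the source of the transcript models are not given in the sources used here. Each table lists 35854 models of 151 to 38630 bases (median 1620), of which 175 had 0 counts in all libraries. The mean fragment length derived from the effective lengths ranged from 198.8 to 220.6 bases. For a model of median effective length, 1 TPM corresponded to 13.5 to 18.2 estimated counts, depending on the library. Values are per transcript model, and levels of near-identical models are uncertain because reads were shared between them.

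None of the identifiers could be named: 0 of 35854 occurred in the reference gene table of 38920 entries. Tests of gene lists were therefore not run, and the reference was not used for coordinates. Transcripts were named by a rule: for each comparison, up to 2 with the largest rise and 2 with the largest fall among those with adjusted p under 0.05, a mean of at least 10 CPM (library-scaled counts) on the higher side and no overlap between the libraries of the sides. The report prints some or all of these for each comparison. Transcripts named for abundance, and those named for the adult, were chosen after their values were seen.

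Estimated counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1). Models with low counts were removed with filterByExpr by stage, which left 30661, and libraries were scaled with TMM (factors 0.6 to 1.34). A quasi-likelihood model with trended dispersion and 1 coefficient per stage was fitted to all 31 libraries (15 residual degrees of freedom). Contrasts were made between consecutive stages and between the means of the gastrula and blastula stages, of the larval and gastrula stages, and of late larvae (Spengel, Agassiz) and early larvae (72 hpf tornaria, Heider), each as the mean of the fitted log levels of its stages with equal weight. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. A stage with 1 library, by design or with a replicate left out, was assumed to vary like the others. The adult was compared with the transforming larva without a test.

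The groups, contrasts, tests, thresholds, naming rule and most of the other settings tried were fixed before the data were examined. The quasi-likelihood fit was changed afterwards: the first fit, edgeR's without a trended dispersion, had been run and its counts seen when 4 ways of fitting were compared on simulated data. On simulated data with 100 transcripts changed 2-fold and 100 changed 4-fold, false calls made up 33.6% of the calls from Krohn to Spengel with the first fit and 6.8% with the trended dispersion, and 50.3% and 8.9% from Agassiz to transforming larvae. For gastrula over blastula they were 6.9% and 5.6%. With the trended dispersion, 12% of 2-fold and 70% of 4-fold changes were called from Krohn to Spengel, 11% and 40% from Agassiz to transforming larvae, and 40% and 94% for gastrula over blastula. The simulated counts gave each transcript the same spread at all stages, estimated from the fit with the trended dispersion. The spread between the real libraries was unequal between stages, so that these shares may not hold for the real data.

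A transcript was counted as detected at 1 TPM, and also at 10 counts after thinning each library to 11539869 counts. Levels are TMM-scaled CPM with the SD between libraries. Fold changes against a group at 0 counts are lower bounds with the group's summed counts set to 3, and ratios against 1 to 3 summed counts are given with exact conditional 95% intervals, which cover counting error only. Libraries were compared by Pearson's r on log2(TPM + 1). The peak of a transcript was the stage with the highest mean CPM, and tau was computed over the stage means. Overlaps between lists were tested with Fisher's exact test, and compared with 10000 sets matched on mean CPM in 40 bins. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, with seed 20240 for random draws.

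Whether replicate numbers pair libraries across stages was checked from the correlation of each library's deviations from its stage mean, on edgeR's log2 CPM with a prior count of 2 (the closing section uses log2(CPM + 1) for the same 15257 transcripts). From early gastrula to mid gastrula before mesoderm migration each library correlated best with its own number (0.46, 0.63 and 0.74), so that these numbers mark pairs. With the replicate number as a block this transition had 2971 calls against 2876 without it. Same-numbered libraries also deviated together from late gastrula to 72 hpf tornaria (0.63) and from late blastula to early gastrula (0.31 and 0.6). In the latter, late blastula replicate 1 correlated best with early gastrula replicate 3. Late blastula and late gastrula did so too (0.42). From mid gastrula before to after mesoderm migration the correlations were -0.04 and -0.09, so that pairs are not shown there. The deposited names number the libraries after migration otherwise than the titles used here. For that stage this check and the block therefore rest on uncertain numbers. With the block, late gastrula to 72 hpf tornaria had 1321 calls against 1193, and late blastula to early gastrula 2586 against 2712.

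The alternatives were DESeq2 1.42.0 size factors in the same fit, the DESeq2 Wald test, no filter on low counts, adjusted p alone, the replicate number as a block, only the libraries compared, a fit with every library of a phase as a replicate, other detection levels and pseudocounts, Spearman's correlation, stage means in TPM, and leaving out each replicate in turn. Alternatives chosen after seeing the data were the first edgeR fit, the block with only the libraries compared, 1 library per stage for peaks, DESeq2 size factors for the adult, and further settings of the overlap. A transcript to which DESeq2 gave no adjusted p was counted as not called. Overlaps by the DESeq2 Wald test used the 21736 transcripts with an adjusted p in both comparisons, against 30661 in the main fit.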

Results

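Whole animals of the acorn worm Ptychodera flava, a hemichordate that develops through a planktonic larva called the tornaria, were profiled by RNA sequencing at 16 stages from the unfertilized egg to the adult. The 31 libraries comprised 1 library of unfertilized eggs, 16 of embryonic stages, 12 of larval stages, 1 of transforming larvae and 1 of an adult. The embryonic stages were 16-32 cell embryos, early and late blastulae, early gastrulae, mid gastrulae before and after mesoderm migration, and late gastrulae. The larval stages were tornaria larvae at 72 hours post fertilization (hpf) and the Heider, Meschnikoff, Krohn, Spengel and Agassiz stages, which are named stages of the tornaria. Early gastrula and mid gastrula before mesoderm migration had 3 libraries each, 11 stages had 2, and the egg, the transforming larva and the adult had 1, so that differences involving these 3 stages have no replicate check of their own. The total of estimated counts per library ranged from 11539946 to 17288661. Each library gave a value for 35854 transcript models, which are named here by the identifiers of the files because 0 of them occurred in the reference gene table. All 17 pairs of libraries of 1 stage differed by more than counting noise (chi-square per degree of freedom of at least 4.31), so that none repeats the values of another, and each was counted as a sample because the labels call them biological replicates. The spread was unequal: this value was 4.31 at the 16-32 cell stage, 36.69 at Meschnikoff, 40.12 at Krohn and 80.48 at Heider. It was 48.62 for early gastrula replicates 2 and 3. The fit used 1 spread per transcript for all stages.

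The number of detected transcripts was higher in larvae than in embryos and highest in the adult. The egg library held 13437 transcripts at a TPM of 1 or more, the embryonic libraries 16611 ± 1617 (SD, n = 16), the larval libraries 21767 ± 1262 (SD, n = 12), the transforming larva 22409 and the adult 24364. Every larval library, at 19286 to 23448 transcripts, lay above every embryonic library, at 13532 to 18859. Within the embryo the number went from 13580 ± 67.2 (SD, n = 2) at the 16-32 cell stage to 18704 ± 219 (SD, n = 2) in the late gastrula, and within the larva the step from 72 hpf tornaria (19602 ± 446, SD, n = 2) to Heider (21782 ± 214, SD, n = 2) was larger than the spread of either pair. With all libraries thinned to 11539869 counts and a minimum of 10 counts, the numbers were 14406 in the egg, 14227 ± 7.1 at the 16-32 cell stage (SD, n = 2), 17225 ± 1559 in embryos, 21936 ± 1091 in larvae, 22792 in the transforming larva and 24917 in the adult.

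Most transcripts present in the egg were still present at every later stage. Of the 13437 egg transcripts, between 91.1% (late blastula) and 95.9% (Heider) reached a stage mean of 1 TPM at each later stage, and 10801 did so at all of them. Egg transcripts made up 44.6% of the 30145 transcripts that reached 1 TPM at any stage. Among the later stages, first detections were most numerous at the early blastula (2176), Heider (2106) and the adult (1987).

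The egg library was dominated by few transcripts. Its 100 most abundant transcripts held 56.5% of TPM, against 42.4 ± 5.84% in the blastula stages (SD, n = 4), 27.8 ± 1.19% in the gastrula stages (SD, n = 10), 26.2 ± 2.70% in the larval stages (SD, n = 12), 26.3% in the transforming larva and 29.3% in the adult. A single model of 312 bases, TCONS_00010708, held 17.35% of TPM in the egg, 12.06 ± 0.97% at the 16-32 cell stage, 13.67 ± 0.47% in the early blastula and 6.42 ± 0.83% in the late blastula (SD, n = 2 each). Its share was 0.795 ± 0.158% in the early gastrula (SD, n = 3), 0.0087 ± 0.0068% in the late gastrula and 0.108 ± 0.151% in the 72 hpf tornaria (SD, n = 2 each). TPM weights short models more than counts do. The 100 transcripts with the most counts, ranked apart from those by TPM, held 37.7% of estimated counts in the egg. They held 22.8 ± 3.33% in the embryonic libraries (SD, n = 16) and 19.7 ± 1.33% in the larval ones (SD, n = 12). In the embryonic libraries the 100 most abundant by TPM held 33.3 ± 7.89% of TPM (SD, n = 16).

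**Figure D1:**
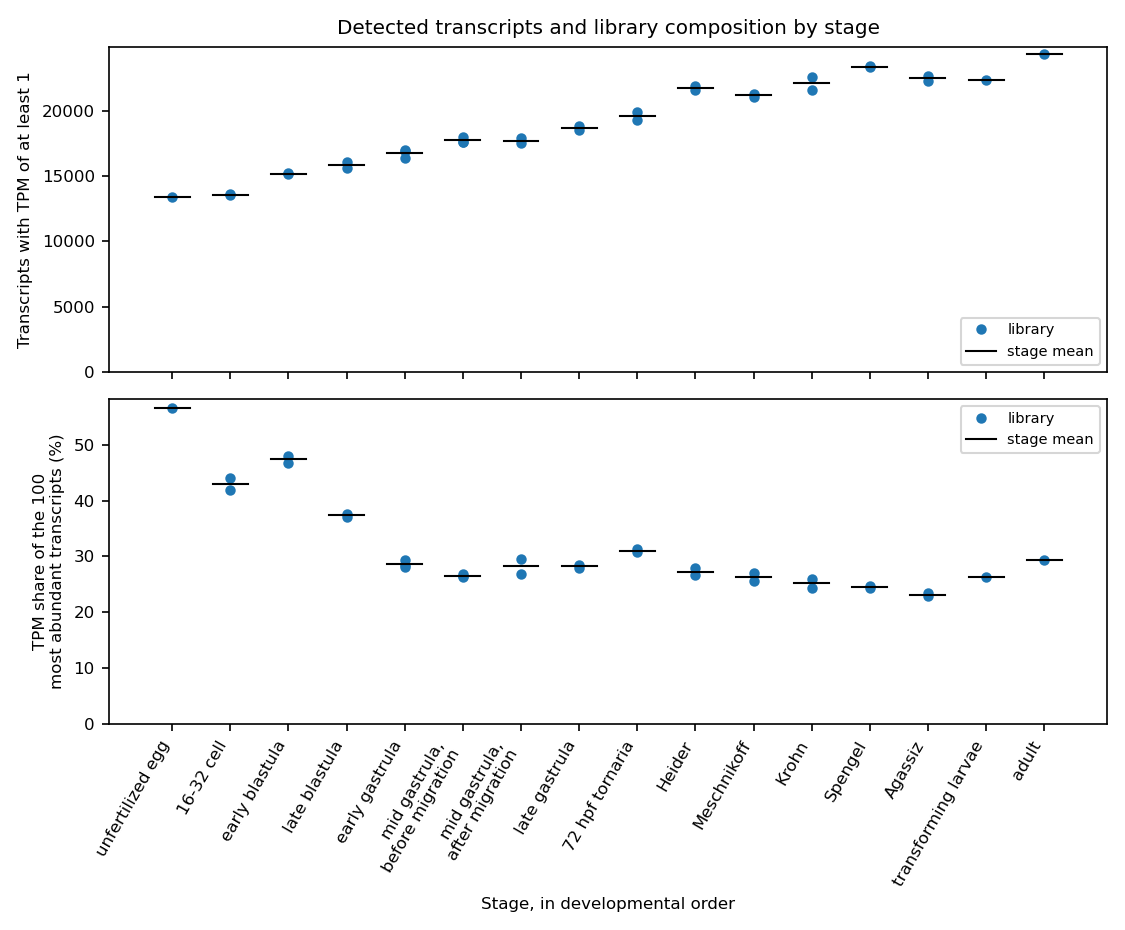
Number of transcripts with TPM of at least 1 (upper panel) and share of TPM held by the 100 most abundant transcripts in percent (lower panel) for each of the 31 libraries, with stages in developmental order, points for libraries and bars for stage means. The number of detected transcripts ran from 13437 in the egg to 24364 in the adult, and the share held by the most abundant transcripts was highest in the egg at 56.5%.

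Libraries were on average more alike within the embryonic and within the larval stages than between them, without a break at the border of the 2. Pearson's r across transcripts on the log2(TPM + 1) scale averaged 0.893 among embryonic libraries, 0.905 among larval libraries and 0.759 between them (ranges 0.741 to 0.996, 0.797 to 0.983 and 0.619 to 0.969), where transcripts are not independent replicates and no test was made. The 72 hpf tornaria was closer to the late gastrula (0.955 to 0.969) than to Heider (0.910 to 0.942). Libraries of 1 stage had r of 0.978 ± 0.011 (SD over 17 pairs), with 0.958 as the lowest. Between consecutive stages the lowest values were those from transforming larva to adult (0.807, 1 pair), from 16-32 cell to early blastula (0.897 ± 0.009, SD over 4 pairs), from Spengel to Agassiz (0.900 ± 0.012, SD over 4 pairs) and from 72 hpf tornaria to Heider (0.926 ± 0.014, SD over 4 pairs), each below the lowest value within any stage. The closest stages were the mid gastrula after mesoderm migration and the late gastrula (0.977 ± 0.005, SD over 4 pairs), within the range of replicates. For 4 libraries with replicates the closest library was of another stage: mid gastrula before mesoderm migration replicate 2 (0.982 with replicate 2 after migration), late gastrula replicate 2 (0.982 with mid gastrula after migration replicate 3), Heider replicate 1 (0.977 with Meschnikoff replicate 1) and Krohn replicate 2 (0.974 with Meschnikoff replicate 2).

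**Figure D2:**
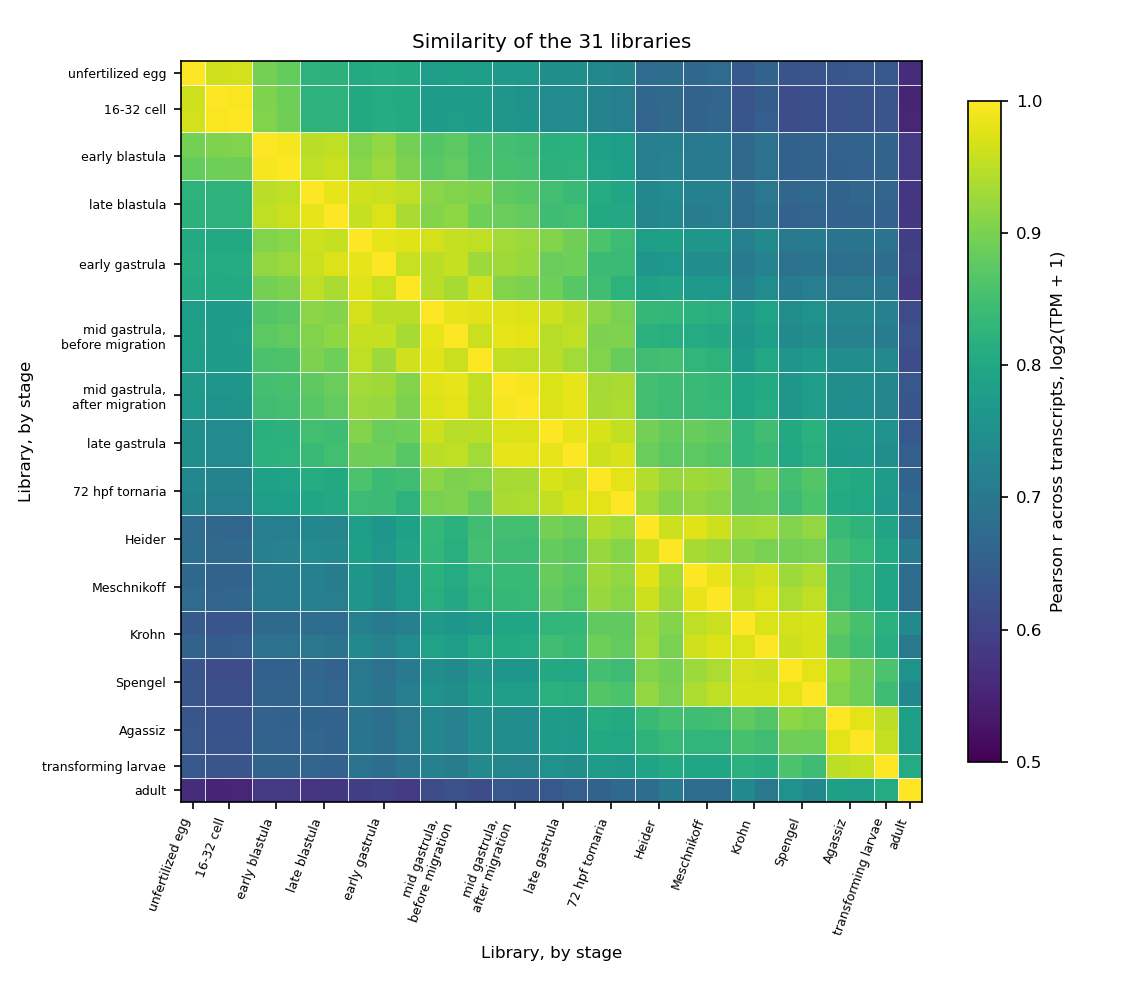
Pearson's r across transcripts on the log2(TPM + 1) scale for every pair of the 31 libraries, with libraries ordered by stage on both axes, white lines between stages and the colour scale running from 0.5 to 1. Mean r is 0.893 among embryonic libraries, 0.905 among larval ones and 0.759 between them, while late gastrula and 72 hpf tornaria libraries reach 0.969, and the adult is closest to the transforming larva (0.807).

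Differences between consecutive stages were tested to show when in development expression changed, over the 30661 transcripts that passed the filter on low counts. A transcript was called when edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05 and the change was at least 2-fold. In all, 19582 transcripts (63.9%) were called in at least 1 of the 14 transitions and 11079 in none. Calls were most numerous from 16-32 cell to early blastula (9546), and numbered 5067 from Spengel to Agassiz, 4537 from 72 hpf tornaria to Heider and 114 from Krohn to Spengel. By the naming rule, for each transcript named for a tested comparison every library of the side with the higher level lay above every library of the other side.

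**Figure D3:**
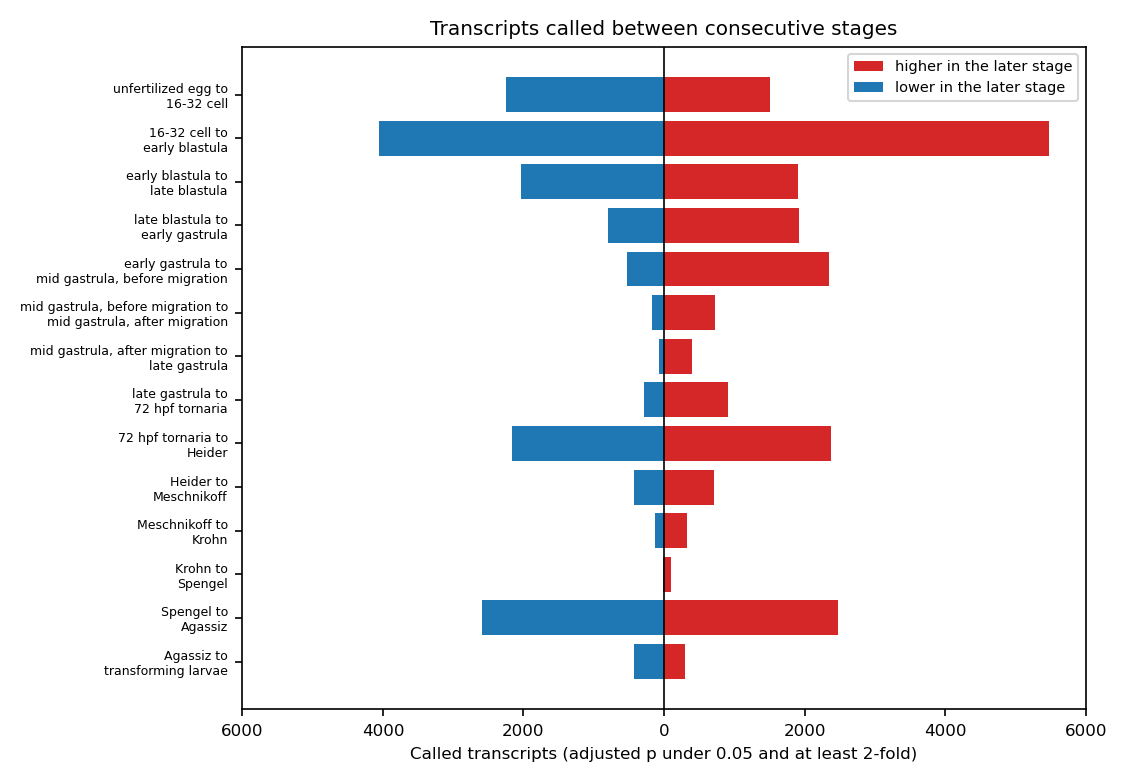
Transcripts called between each pair of consecutive stages by edgeR's quasi-likelihood test, with those higher in the later stage drawn to the right and those lower drawn to the left of 0. The longest bars, at 5485 higher and 4061 lower transcripts, are those from 16-32 cell to early blastula, and the shortest, at 98 and 16, those from Krohn to Spengel.

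From the unfertilized egg to the 16-32 cell stage, more transcripts fell than rose. Of 3767 called transcripts, 2252 were lower and 1515 higher at the 16-32 cell stage, and 379 were lower by at least 8-fold against 53 that were higher. TCONS_00017383 had 0 counts in the egg and 36.8 ± 13.7 TMM-scaled CPM (SD, n = 2) at the 16-32 cell stage, which was at least 97.7-fold higher (edgeR adjusted p = 2.41e-06). TCONS_00045803 fell from 13.7 CPM to 0.229 ± 0.178 CPM (SD, n = 2), a log2 fold change of -5.81 (SE 1.00, edgeR adjusted p = 0.000312). The single egg library was assumed to vary like the replicated stages, and the fit on only the libraries compared called 2453 higher and 2376 lower.

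From the 16-32 cell stage to the early blastula, expression changed more widely than at any other of the 14 tested transitions. Of 9546 called transcripts (31.1% of those tested), 5485 rose and 4061 fell, and 2857 rose by at least 8-fold against 628 that fell as far. TCONS_00046357 had 0 counts in both 16-32 cell libraries and 109 ± 1.71 CPM (SD, n = 2) in the early blastula, at least 761-fold higher (edgeR adjusted p = 1.03e-07). TCONS_00003371, also at 0 in both, reached 56.5 ± 14.2 CPM (SD, n = 2), at least 398-fold higher (edgeR adjusted p = 4.30e-07). TCONS_00027398 fell from 46.7 ± 5.96 to 0.333 ± 0.0421 CPM (SD, n = 2 each), a log2 fold change of -7.09 (SE 0.84, edgeR adjusted p = 7.41e-07). TCONS_00028777 had a log2 fold change of -6.40 (SE 1.23, edgeR adjusted p = 0.000712) and did not pass the DESeq2 Wald test.

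Between the early and late blastula, rises and falls were about equal. Of 3937 called transcripts, 1904 rose and 2033 fell, while among changes of at least 8-fold 567 rose and 195 fell. TCONS_00030528 went from 0 counts to 18.6 ± 5.69 CPM (SD, n = 2), at least 130-fold higher (edgeR adjusted p = 2.78e-08). TCONS_00053350, also from 0 counts, reached 20.9 ± 8.05 CPM (SD, n = 2), at least 145-fold higher (edgeR adjusted p = 0.00558), a call that was lost without either early blastula library. TCONS_00011354 fell from 24.4 ± 6.07 to 0.657 ± 0.416 CPM (SD, n = 2 each), a log2 fold change of -5.20 (SE 0.77, edgeR adjusted p = 0.000403), and was not called by the DESeq2 Wald test. With DESeq2 size factors in the same fit, 2081 rose and 1853 fell.

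With the onset of gastrulation, rises outnumbered falls. From late blastula to early gastrula 2712 transcripts were called, 1922 higher (70.9%) and 790 lower. TCONS_00038769 went from 1 count over both late blastula libraries to 138 ± 78.8 CPM (SD, n = 3), a ratio of 2910 with a 95% counting interval of 521 to 115000 (edgeR adjusted p = 5.94e-08). TCONS_00001040, among the abundant transcripts of the blastula at 701 ± 251 CPM (SD, n = 2), fell to 15 ± 8.55 CPM (SD, n = 3), a log2 fold change of -5.54 (SE 0.41, edgeR adjusted p = 3.26e-08). Adjusted p alone, without the fold threshold, gave 4519 calls, 62.3% higher, and the fit on only the 5 libraries compared gave 1379.

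From the early gastrula to the mid gastrula before mesoderm migration, most called transcripts rose. Of 2876 called transcripts, 2347 rose (81.6%) and 529 fell, with 779 higher and 50 lower by at least 8-fold. TCONS_00024086 went from 1 count in 3 libraries to 37.6 ± 5.61 CPM (SD, n = 3), a ratio of 1450 with a 95% counting interval of 260 to 57400 (edgeR adjusted p = 1.84e-11). TCONS_00018388 went from 1 count to 33.4 ± 1.79 CPM (SD, n = 3), a ratio of 1290 (232 to 51100; edgeR adjusted p = 1.12e-11). TCONS_00029042 fell from 16.7 ± 6.47 to 0.558 ± 0.566 CPM (SD, n = 3 each), a log2 fold change of -4.96 (SE 0.50, edgeR adjusted p = 3.25e-06). Adjusted p alone gave 5439 calls, 57.9% higher, and the fit on only the 6 libraries compared gave 1824. With the replicate number as a block, the fit on those libraries gave 3462 (chosen after seeing the data).

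From before to after mesoderm migration, fewer transcripts changed, again mostly upward. Of 900 called transcripts, 732 rose (81.3%) and 168 fell. TCONS_00008867 rose from 0.7 ± 0.289 (SD, n = 3) to 10.3 ± 4.05 CPM (SD, n = 2), a log2 fold change of 3.86 (SE 0.31, edgeR adjusted p = 2.60e-06). TCONS_00052949 had a log2 fold change of -6.26 (SE 1.45, edgeR adjusted p = 0.0162), at 38.7 ± 44.7 CPM before migration (SD, n = 3), and its call was lost with only the libraries compared and when any 1 of 3 libraries was left out. The count was 1391 by the DESeq2 Wald test (68.7% higher), 1487 by adjusted p alone and 469 with only the libraries compared. It was 497 without replicate 2 and 218 without replicate 3 of the later stage.

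Between the mid gastrula after mesoderm migration and the late gastrula, 471 transcripts were called, 399 higher (84.7%) and 72 lower. TCONS_00006493 rose from 0.178 ± 0.0459 to 10.5 ± 6.41 CPM (SD, n = 2 each), a log2 fold change of 5.81 (SE 0.72, edgeR adjusted p = 0.000307). TCONS_00046044 fell from 36.1 ± 13.3 to 1.34 ± 0.852 CPM (SD, n = 2 each), a log2 fold change of -4.76 (SE 0.78, edgeR adjusted p = 0.00238), a call that was lost without late gastrula replicate 1. The count was 944 by the DESeq2 Wald test and 1119 with only the libraries compared. It was 84 without mid gastrula replicate 2, 112 without mid gastrula replicate 3, 204 without late gastrula replicate 1 and 183 without late gastrula replicate 2.

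Over the blastula and gastrula as a whole, 9100 transcripts differed between the mean of the 4 gastrula stages and the mean of the 2 blastula stages. Of these, 5852 were higher in the gastrula (64.3%) and 3248 lower, with 2637 higher and 523 lower by at least 8-fold. TCONS_00007574 had 0 counts in all 4 blastula libraries and 29.5 ± 22.3 CPM in the gastrula (SD, n = 10), at least 413-fold higher (edgeR adjusted p = 2.17e-10). TCONS_00014425 went from 1 count to 70.7 ± 46.9 CPM (SD, n = 10), a ratio of 3070 with a 95% counting interval of 551 to 121000 (edgeR adjusted p = 8.17e-11). TCONS_00001040 fell from 891 ± 263 (SD, n = 4) to 5.02 ± 8.01 CPM (SD, n = 10), a log2 fold change of -9.54 (SE 0.31, edgeR adjusted p = 1.57e-14), and TCONS_00029042 from 183 ± 30.4 to 5.2 ± 8.49 CPM, a log2 fold change of -9.12 (SE 0.37, edgeR adjusted p = 6.64e-12). Fold changes of means over stages are fitted as means of the log levels of the stages, so they differ from the ratios of the pooled levels, 177 and 38 for these 2 transcripts. Adjusted p alone gave 14191 calls, of which 55.9% were higher.

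From the late gastrula to the 72 hpf tornaria, 1193 transcripts were called, 909 higher (76.2%) and 284 lower. TCONS_00018691 went from 0 counts to 37.4 ± 18.9 CPM (SD, n = 2), at least 311-fold higher (edgeR adjusted p = 0.000594), and was also among the transcripts that rose most from gastrula to larva. TCONS_00005451 fell from 35.0 ± 27.5 to 0.680 ± 0.145 CPM (SD, n = 2 each), a log2 fold change of -5.66 (SE 0.47, edgeR adjusted p = 8.03e-07). The count was 403 without late gastrula replicate 1, 593 without late gastrula replicate 2, 787 without tornaria replicate 1 and 576 without tornaria replicate 2.

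More transcripts were called from the 72 hpf tornaria to the Heider stage than at the next 3 larval transitions. Of 4537 called transcripts, 2374 rose (52.3%) and 2163 fell, with 1002 higher and 351 lower by at least 8-fold. TCONS_00050419 went from 0 counts to 10.9 ± 3.41 CPM (SD, n = 2), at least 110-fold higher (edgeR adjusted p = 6.03e-05). TCONS_00026516 went from 0 counts to 26.6 ± 36.9 CPM (SD, n = 2), at least 285-fold higher on summed counts (edgeR adjusted p = 0.00603), and was not called with only the libraries compared. Of its 1130 Heider counts, 1121 came from 1 library, so that this bound rests on that library. The transcripts with the largest falls, TCONS_00010708 and TCONS_00013972 (edgeR adjusted p = 0.000437 and 0.00076), had 3094 and 4823 counts in tornaria replicate 1 but 21 and 23 in replicate 2, and at most 1 in each Heider library; neither was called with only the libraries compared. Both were abundant in the egg, and belong to 28 egg-abundant transcripts that had a median of 0.649% of their egg level in tornaria replicate 1 and 0.00328% in replicate 2. With DESeq2 size factors in the same fit the median log2 fold change went from 0.03 to 0.16 and 62.7% of 4460 calls were higher, while only the libraries compared gave 1922 calls, 47.6% higher, and adjusted p alone gave 42.3% higher. The count was 2992 (39.4% higher) without tornaria replicate 1, 2280 (38.6% higher) without tornaria replicate 2 and 2791 (49.2% higher) without Heider replicate 2, and 46.9% were higher without Heider replicate 1.

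From Heider to Meschnikoff 1143 transcripts were called, 718 higher (62.8%) and 425 lower. TCONS_00030076 rose from 1.19 ± 0.618 to 512 ± 184 CPM (SD, n = 2 each), a log2 fold change of 8.75 (SE 0.63, edgeR adjusted p = 1.05e-07). TCONS_00027632 had the largest fall, with a log2 fold change of -6.95 (SE 1.44, edgeR adjusted p = 0.0109), at 117 ± 148 CPM in Heider (SD, n = 2), and was not called without Heider replicate 2 or without either Meschnikoff library. The fit on only the libraries compared called 0 by edgeR, with 4232 at an unadjusted p under 0.05, against 1569 by the DESeq2 Wald test and 2243 by edgeR's fit without a trended dispersion (chosen after seeing the data). The count was 2527 without Heider replicate 1, 132 without Heider replicate 2, 703 without Meschnikoff replicate 1 and 153 without Meschnikoff replicate 2.

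From Meschnikoff to Krohn 453 transcripts were called, 324 higher (71.5%) and 129 lower. Rises and falls were equal in number without Meschnikoff replicate 1. Rises were a smaller majority without Meschnikoff replicate 2 or Krohn replicate 2, but not without Krohn replicate 1. TCONS_00032853 rose from 0.134 ± 0.0376 to 58.7 ± 49.7 CPM (SD, n = 2 each), a log2 fold change of 8.69 (SE 1.05, edgeR adjusted p = 0.000432). TCONS_00025036 fell from 11.2 ± 8.61 CPM (SD, n = 2) to 0 counts in both Krohn libraries, at least 133-fold lower (edgeR adjusted p = 9.75e-06). With only the libraries compared edgeR called 0, with 4020 at an unadjusted p under 0.05, against 806 by the DESeq2 Wald test and 1385 by edgeR's fit without a trended dispersion (chosen after seeing the data). The count was 28 without Meschnikoff replicate 1, 234 without Meschnikoff replicate 2, 186 without Krohn replicate 1 and 692 without Krohn replicate 2.

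From Krohn to Spengel 114 transcripts were called, 98 higher and 16 lower. TCONS_00050772 and TCONS_00050773 rose most, from 4.71 ± 5.79 to 258 ± 134 CPM and from 5.41 ± 7.14 to 184 ± 86.6 CPM (SD, n = 2 each), with log2 fold changes of 5.79 (SE 1.05, edgeR adjusted p = 0.0193) and 5.11 (SE 0.96, edgeR adjusted p = 0.0287). Neither was called by the DESeq2 Wald test, with only the libraries compared or without Spengel replicate 2, and TCONS_00050773 was not called without Spengel replicate 1 either. The count was 333 by the DESeq2 Wald test, 512 in edgeR's fit without a trended dispersion (chosen after seeing the data), 177 with the replicate number as a block and 1 with only the libraries compared. It was 452 (43.8% higher) without Krohn replicate 1, 37 without Krohn replicate 2 and 46 without Spengel replicate 1.

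Across the whole span, 14687 transcripts (47.9% of those tested) differed between the mean of the 6 larval stages and the mean of the 4 gastrula stages. Of these, 9146 were higher in larvae (62.3%) and 5541 lower, with 4048 higher and 779 lower by at least 8-fold. TCONS_00052099 had 0 counts in all 10 gastrula libraries and 117 ± 162 CPM in larvae (SD, n = 12), at least 5430-fold higher (edgeR adjusted p = 3.27e-07), and TCONS_00018691 rose from 0.121 ± 0.202 (SD, n = 10) to 465 ± 418 CPM (SD, n = 12), a log2 fold change of 12.49 (SE 0.63, edgeR adjusted p = 6.66e-11). TCONS_00045325 fell from 2180 ± 2160 (SD, n = 10) to 11.9 ± 26.9 CPM (SD, n = 12), a log2 fold change of -10.66 (SE 0.46, edgeR adjusted p = 5.87e-14), and TCONS_00005451 from 724 ± 643 to 0.258 ± 0.224 CPM, a log2 fold change of -10.50 (SE 0.23, edgeR adjusted p = 1.26e-17). The pooled levels of these 2 had ratios of 208 and 2900, against fitted means over the log levels of the stages. The median log2 fold change of all tested transcripts was 0.38, and 0.63 with DESeq2 size factors in the same fit, under which 71.4% of 14620 calls were higher; the DESeq2 Wald test gave 72.4% of 14996.

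Between early and late larvae, 9424 transcripts differed when the mean of Spengel and Agassiz was set against the mean of 72 hpf tornaria and Heider. Of these, 5842 were higher in late larvae (62.0%) and 3582 lower, with 2795 higher and 740 lower by at least 8-fold. TCONS_00031413 rose from 0.208 ± 0.254 to 1140 ± 730 CPM (SD, n = 4 each), a log2 fold change of 14.07 (SE 1.19, edgeR adjusted p = 4.79e-07), and TCONS_00024542 from 0 counts to 82.8 ± 28.1 CPM (SD, n = 4), at least 1970-fold higher (edgeR adjusted p = 6.65e-07). TCONS_00034240 fell from 20.8 ± 17.7 CPM (SD, n = 4) to 0 counts in all 4 late libraries, at least 483-fold lower (edgeR adjusted p = 2.13e-10), and TCONS_00053046 from 238 ± 242 to 0.066 ± 0.0234 CPM (SD, n = 4 each), a log2 fold change of -10.59 (SE 0.87, edgeR adjusted p = 1.44e-08). The pooled levels of TCONS_00031413 and TCONS_00053046 had ratios of 4690 and 3140. DESeq2 size factors moved the median log2 fold change from -0.01 to 0.14, with 68.8% of 9355 calls higher. The count was 5354 (67.6% higher) in a fit with every library of a phase as a replicate and 14331 (49.7% higher) with adjusted p alone.

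From Spengel to Agassiz, near the end of larval life, expression changed widely in both directions. Of 5067 called transcripts (16.5% of those tested), 2483 rose and 2584 fell, with 824 higher and 899 lower by at least 8-fold. TCONS_00038471 went from 0 counts to 19.8 ± 2.72 CPM (SD, n = 2), at least 258-fold higher (edgeR adjusted p = 6.24e-05), and TCONS_00007747 from 0 counts to 15.3 ± 8.53 CPM, at least 203-fold higher (edgeR adjusted p = 0.0003); the DESeq2 Wald test called neither. TCONS_00010386 fell from 124 ± 3.49 to 0.196 ± 0.0484 CPM (SD, n = 2 each), a log2 fold change of -9.25 (SE 1.25, edgeR adjusted p = 3.39e-05), and TCONS_00025111 from 64.7 ± 17.5 to 0.198 ± 0.127 CPM, a log2 fold change of -8.31 (SE 0.91, edgeR adjusted p = 9.96e-06). The count was 3310 (45.4% higher) without Spengel replicate 2 and 2913 (57.2% higher) without Agassiz replicate 2.

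At metamorphosis, from Agassiz to transforming larvae, 725 transcripts were called, of which 305 rose (42.1%) and 420 fell. TCONS_00030674 rose from 1.84 ± 2.21 (SD, n = 2) to 556 CPM, a log2 fold change of 8.25 (SE 0.71, edgeR adjusted p = 4.03e-06), and TCONS_00006415 from 0.704 ± 0.914 to 123 CPM, a log2 fold change of 7.42 (SE 1.03, edgeR adjusted p = 0.000412). TCONS_00050773, which had risen from Krohn to Spengel, fell from 261 ± 132 CPM (SD, n = 2) to 0 counts, at least 1490-fold lower (edgeR adjusted p = 0.00402). TCONS_00050771 fell from 487 ± 204 CPM (SD, n = 2) to 3 counts, a ratio of 2790 with a 95% counting interval of 955 to 13500 (edgeR adjusted p = 0.00219). The single library of transforming larvae was assumed to vary like the replicated stages, and without Agassiz replicate 1 the count was 308 (28.2% higher). It was 1147 (31.5% higher) by the DESeq2 Wald test, 1788 (44.0% higher) with only the libraries compared and 1614 (57.0% higher) in edgeR's quasi-likelihood fit without a trended dispersion, which was chosen after seeing the data.

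The adult library stood far from the transforming larva. Of 13325 transcripts with at least 10 CPM in either library, 883 were at least 8-fold higher and 576 at least 8-fold lower in the adult, with counts under 3 set to 3. TCONS_00041219 had 0 counts in the transforming larva and 23250 in the adult, at least 8220-fold higher. TCONS_00046693 had 1 and 20428 counts, a ratio of 21700 with a 95% counting interval of 3890 to 856000. TCONS_00031413, which had risen from early to late larvae, had 41493 counts in the transforming larva and 12 in the adult, a ratio of 3260 (1870 to 6310), and TCONS_00054152 had 2723 and 3 counts, a ratio of 856 (292 to 4150). With 1 library on each side no test was made. The median log2 ratio of these transcripts was -0.24. With DESeq2 size factors 14515 transcripts reached 10 CPM, with a median of -0.01, and 1115 were higher and 556 lower by at least 8-fold.

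Whether transcripts that rose at gastrulation rose again at metamorphosis was asked with the calls of both comparisons, which share no library. Of the 305 transcripts that rose from Agassiz to transforming larvae, 52 had risen from blastula to gastrula, against 58.2 expected from independent lists (odds ratio 0.87, 95% interval 0.63 to 1.18, two-sided Fisher's exact test across transcripts, p = 0.42), and 69.8 on average (56 to 84) in sets matched on expression level. Of the 420 that fell at metamorphosis, 195 had risen at gastrulation, against 80.2 expected (odds ratio 3.77, 95% interval 3.09 to 4.59, two-sided Fisher's exact test, p = 1.3e-37), and of the 305 that rose, 58 had fallen at gastrulation, against 32.3 expected (odds ratio 2.0, 95% interval 1.47 to 2.68, two-sided Fisher's exact test, p = 1.3e-05). Falls at both times numbered 47, against 44.5 expected (odds ratio 1.06, 95% interval 0.77 to 1.45, two-sided Fisher's exact test, p = 0.69), and by the DESeq2 Wald test their odds ratio was 0.78 (exact test, p = 0.041). The last 3 comparisons were chosen after the data were seen. Transcripts are not independent of each other, so these p-values are too small. Without early gastrula replicate 3 the odds ratio for rises was 1.02, and in edgeR's fit without a trended dispersion it was 0.74 (two-sided Fisher's exact test, p = 0.0012), and that for falls followed by rises 1.12 (p = 0.25 by the same exact test).

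Peaks of expression were spread from the egg to the adult. The stage with the highest mean CPM was the egg or an embryonic stage for 12987 transcripts (42.4%), a larval stage for 8446 (27.5%), the transforming larva for 2812 (9.2%) and the adult for 6416 (20.9%). Stage restriction, measured by the index tau (0 for equal levels at all stages, 1 for expression at a single stage), had a median of 0.34 for transcripts that peaked in the egg or embryo, 0.58 in larvae, 0.72 in the transforming larva and 0.81 in the adult. Of the 5965 transcripts with tau above 0.8, 3274 peaked in the adult. Tau depends on which stages were sampled, because a transcript shared by similar neighbouring stages gets a lower value. Mid gastrula after mesoderm migration and late gastrula had a mean r of 0.977, while transforming larva and adult had 0.807. The transforming larva and the adult also had 1 library each, so the differences in tau cannot be told apart from the sampling. A maximum over stages favours stages with 1 library: in simulated data 32.8% of unchanged transcripts peaked in the 3 single-library stages. Whether the egg and embryo or the larva held more peaks depended on the scale: with stage means in TPM, 10381 transcripts (33.9%) peaked in the egg or embryo and 11090 (36.2%) in larvae. With 1 library kept per stage, 13101 transcripts peaked in the egg or embryo, 8375 in larvae and 6318 in the adult.

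**Figure D4:**
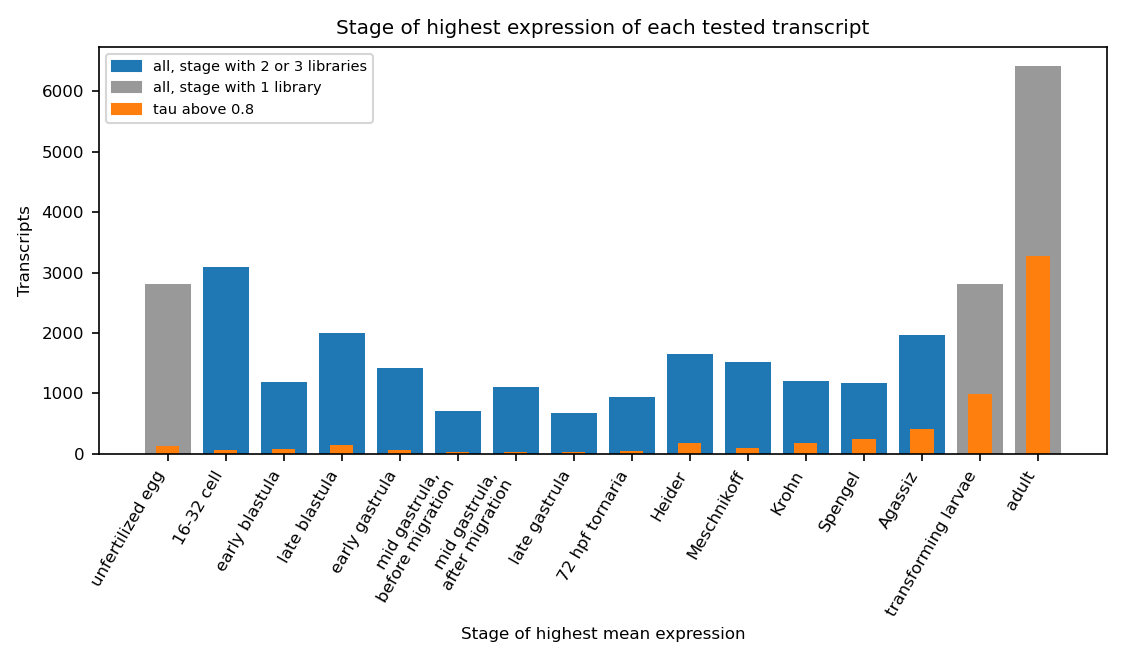
Number of tested transcripts whose highest mean expression fell in each stage, with blue bars for stages with 2 or 3 libraries, grey bars for stages with 1 library and narrow orange bars for the transcripts with tau above 0.8. The adult bar is the tallest at 6416 transcripts, 3274 of them with tau above 0.8.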

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

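The alternatives chosen after seeing the data were edgeR's fit without a trended dispersion, which had been the first fit, the block with only the libraries compared, 1 library per stage, DESeq2 size factors for the adult, and all overlaps but that of rises at both times, and for that one the settings beyond scaling and fold threshold. DESeq2 size factors in edgeR and no filter on low counts left all 17 counts of calls within 1.5 times the reported ones. Of 824 values of named transcripts under the alternatives, 767 passed the same threshold in the same direction, 57 no longer passed it and 0 reversed. These transcripts had been chosen from the same libraries for large changes without overlap between the sides. Reversals were therefore unlikely from the outset, and their absence is no separate check. With adjusted p alone the count was 4519 for late blastula to early gastrula, 5439 for early to mid gastrula, 1487 for mid gastrula before to after mesoderm migration, 14191 for gastrula over blastula and 14331 for late over early larvae. The replicate block gave 177 for Krohn to Spengel, where the numbers are not shown to mark pairs; for early to mid gastrula, where they are, the block with only the libraries compared gave 3462. Only the libraries compared gave, by edgeR, 1379 for late blastula to early gastrula, 1824 for early to mid gastrula, 469 for before to after migration, 1119 for mid to late gastrula, 1922 for 72 hpf tornaria to Heider, 1 for Krohn to Spengel and 1788 for Agassiz to transforming larvae. It gave 0 for Heider to Meschnikoff and 0 for Meschnikoff to Krohn, with 4232 and 4020 transcripts at an unadjusted p under 0.05, where the DESeq2 Wald test on all libraries called 1569 and 806. Every library of a phase as a replicate gave 5354 for late over early larvae, where differences between stages count as spread. The DESeq2 Wald test gave 1391 for before to after migration, 944 for mid to late gastrula, 806 for Meschnikoff to Krohn, 333 for Krohn to Spengel and 1147 for Agassiz to transforming larvae. edgeR's fit without a trended dispersion gave 2243 for Heider to Meschnikoff, 1385 for Meschnikoff to Krohn, 512 for Krohn to Spengel and 1614 for Agassiz to transforming larvae, and an odds ratio of 0.74 for the overlap of rises at gastrulation and metamorphosis (two-sided Fisher's exact test, p = 0.0012). For a fall followed by a rise it gave 1.12 in place of 2.0 (exact test, p = 0.25). For falls at both times, 1.06 became 0.92 with that fit and 0.78 by the DESeq2 Wald test. The odds ratio for rises reversed to 1.02 without early gastrula replicate 3. Apart from the phase fit, the cause of these changes was not tested. Detection at 0.5 TPM gave 18639 transcripts in embryonic and 24232 in larval libraries, and at 2 TPM 14496 and 19025, because the level itself moves the number. With stage means in TPM more transcripts peaked in larvae (11090) than in egg and embryo (10381), the reverse of the reported order, and the cause was not tested. The share of the 100 most abundant transcripts, ranked by counts, was 22.8% of counts in embryos and 19.7% in larvae. Tests of gene lists, with their alternative correlation, were not run because no transcript could be named. In simulated data at this depth, with the same spread at all stages, 12% of 2-fold changes were called from Krohn to Spengel.

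Leaving out 1 library at a time gave 2949 to 3090 calls for egg to 16-32 cell, 7986 to 8891 for 16-32 cell to early blastula, 2754 to 3351 for early to late blastula, 1837 to 3120 for late blastula to early gastrula, 2442 to 3106 for early to mid gastrula, 8418 to 9152 for gastrula over blastula, 13584 to 14896 for larvae over gastrula and 8361 to 9171 for late over early larvae. It gave 218 (without mid gastrula after mesoderm migration replicate 3; 497 without replicate 2) to 959 for before to after migration. For mid to late gastrula it gave 84 (without mid gastrula replicate 2), 112 (without mid gastrula replicate 3), 183 (without late gastrula replicate 2) and 204 (without late gastrula replicate 1). For late gastrula to 72 hpf tornaria it gave 403 and 593 without late gastrula replicates 1 and 2, and 787 and 576 without tornaria replicates 1 and 2. For 72 hpf tornaria to Heider it gave 2280 (without tornaria replicate 2), 2992 (without tornaria replicate 1), 2791 (without Heider replicate 2) and 4532. For Heider to Meschnikoff it gave 2527 and 132 without Heider replicates 1 and 2, and 703 and 153 without Meschnikoff replicates 1 and 2. For Meschnikoff to Krohn it gave 28 and 234 without Meschnikoff replicates 1 and 2, and 186 and 692 without Krohn replicates 1 and 2. For Krohn to Spengel it gave 452 and 37 without Krohn replicates 1 and 2, and 46 without Spengel replicate 1. For Spengel to Agassiz it gave 2913 (without Agassiz replicate 2), 3310 (without Spengel replicate 2) and at most 4005, and for Agassiz to transforming larvae 308 (without Agassiz replicate 1) and 583. Peaks ranged from 12804 to 13138 for egg and embryo, 8314 to 8673 for larvae and 6320 to 6481 for the adult. The odds ratio for rises at both times ranged from 0.68 to 1.02, that for a rise followed by a fall from 3.25 to 4.25, that for a fall followed by a rise from 1.82 to 2.37 and that for falls at both times from 0.84 to 1.12.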

Other observations

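Among the tests in this part, those of kept maternal RNA, early blastula material, egg material and a staging offset, the counts over other splits, the overlaps other than that of rises at both times and the comparisons with the Spengel to Agassiz calls were chosen after the results were seen.

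Transcripts abundant in the egg reappeared in 1 of the 2 libraries of 72 hpf tornaria. The 28 transcripts with at least 200 CPM in the egg and under 0.1% of that in Heider had a median of 0.649% of their egg level in replicate 1 (quartiles 0.442 and 0.971), 0.00328% in replicate 2, and 0.0453% and 0.0137% in the late gastrula libraries. The tables argue against maternal RNA kept from the egg, since the higher late gastrula median was 0.07 of that in replicate 1, and against early blastula material, since 13 transcripts of that stage, picked by a rule loosened after their values were seen, had a median share of 0.0216%, 0.033 of that of the egg transcripts. Material or reads from unfertilized eggs may be the source, as the log10 shares had an interquartile range of 0.34, near a single share. Eggs in the sample, reads misassigned between libraries and material of 16-32 cell embryos were not tested apart, and no biological explanation other than kept maternal RNA was tested.

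Early gastrula libraries shared deviations from their stage mean with the mid gastrula library before mesoderm migration of the same number. The mean correlation was 0.64 on log2(CPM + 1) over 15257 transcripts. The mean for other numbers, -0.30, is no separate baseline, because deviations from a stage mean cancel within the stage. The same-number mean was 0.57 with some stage axes removed: late blastula to early gastrula, before to after mesoderm migration, and from there to late gastrula. The axis from early gastrula to mid gastrula before migration was not removed, so that a staging offset stays open. The tables argue against transcript length bias, since the same-number mean was 0.64 with deviations centred within 50 bins of length. Shared parents, culture or handling could be the source, and the labels give none of these, so that no biological explanation was tested.

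Opposite directions at gastrulation and metamorphosis were more frequent than in sets matched on expression level: 195 of the 420 transcripts that fell from Agassiz to transforming larvae had risen at gastrulation, against 81 to 114 (mean 97.2), and 58 of the 305 that rose had fallen, against 22 to 43, though the odds ratio of the latter was 1.12 in place of 2.0 in edgeR's fit without a trended dispersion. Shared directions were not uniformly fewer: falls at both times numbered 47 against 33 to 57, and rises at both times 52 against 56 to 84, where the odds ratio of 0.87 became 1.02 without early gastrula replicate 3. From Spengel to Agassiz, which shares no library with gastrula over blastula, 989 of 2584 falls had risen (515 to 593 in matched sets), 305 of 2483 rises had fallen (229 to 285), 558 rises had risen (538 to 615) and 231 falls had fallen (243 to 301). This comparison shares the Agassiz libraries with that at metamorphosis, so that it is no independent repeat. Of the 420 falls at metamorphosis, 159 had fallen and 96 had risen from Spengel to Agassiz, against 35.4 and 34.0 for independent lists. Expression level as the whole cause of the first overlap is argued against by the upper end of 114. Of simulated sets tied to level alone, 5.5% fell outside their range. Those sets were drawn on the level used for matching, so this checks the procedure only. A difference in the mix of cell types or tissues stays open, and no biological explanation was tested.

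The other splits of the same libraries that were fitted, each as 2 groups, called fewer transcripts than the real ones. Of the possible splits of single libraries, 100 of 1001 were fitted for gastrula over blastula and 100 of 646646 for larvae over gastrula. Over splits of single libraries, which part libraries of a stage, the real and the highest other count were 7447 and 374 for gastrula over blastula (1 of 100 splits as large), 16297 and 7811 for larvae over gastrula (1 of 100) and 5354 and 0 for late over early larvae (1 of 35). With the libraries of a stage kept together, the real split of larvae over gastrula called the most (1 of 100 splits as large). The highest other count was 14459, from the split that exchanged late gastrula and 72 hpf tornaria, and 100 of the 210 possible splits were fitted. Neighbouring stages of a time course resemble each other, which by itself favours a cut between earlier and later stages. These counts therefore cannot exclude chance. Whole stages give too few splits for a share under 0.05 for gastrula over blastula (15 splits, highest other 4862) and late over early larvae (3 splits, highest other 0). For early to mid gastrula the real split called 1824 and the highest other 0, and the 10 splits are too few for a share under 0.05; the other splits that part all 3 pairs called 0 as well.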
